A study of Mus musculus with 18 samples.

How the data were processed

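The deposited values were log2 signals of 41034 probes on 18 arrays and were used as the authors gave them. Per the labels, C10 cells were grown to confluence, kept without serum for 24 h and exposed to the compounds or DMSO, and RNA with a RIN of 7 or more was used, 150 ng per array, with the GeneChip WT PLUS kit and biotin. Per the submitters' processing notes, Partek 6.6 and RMA were used, with no role or order stated. The genome build was not given in the sources used here. Values ran from 0.938 to 13.1, with array medians of 3.35 to 3.43, and were not normalized again.

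Of the probes, 23521 carried 1 gene symbol, 1820 several and 15693 none. Of those with 1 symbol, 23328 matched the reference gene table by Entrez identifier, and 0 symbols changed by the match. For the 1082 genes with more than 1 probe the probe with the highest mean over all arrays was taken, which left 22180 genes, and no dim gene was removed. Genes above the median of all probes (3.38) numbered 12816.

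Linear models with 1 mean per group were fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, residual degrees of freedom 12, prior degrees of freedom 4.52). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Comparisons were fluoranthene, the mixture and the inhibitor with the mixture at 4 h against DMSO, both 8 h groups against DMSO at 4 h, the mixture against fluoranthene at 4 h, the mixture at 8 h against 4 h, the inhibitor with the mixture against the mixture at each time, and the difference between the last pair. Fixed lists of genes (38 lists, 926 entries, of which 846 matched a tested gene) were tested with camera at a preset correlation of 0.01 and at least 5 measured members, and p-values were adjusted over all 304 tests of 8 comparisons. Of these 304, 101 passed and 50 also passed with an estimated correlation. For most lists that passed both ways only the preset p-value is printed, and the estimated one was often much larger. For the immediate early list with the mixture at 4 h the camera adjusted p was 4.59e-40 preset and 0.00178 estimated. Counts within a list were also given with p-values adjusted over the list alone. Some genes are in more than 1 list, so the list tests are not independent. Intervals are 95% intervals of the limma fit. With 3 arrays against 3 the smallest exact two-sided p is 0.1.

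Genes named in the text followed a rule. For each comparison the 10 largest rises and 10 largest falls were taken among called genes whose groups did not overlap (overlap was not asked of the difference between the inhibitor changes), leaving out predicted and unplaced genes, small RNAs and chemosensory receptors. For each list that passed or had at least 3 changed members, up to 4 of the largest changed members were added. A set of 20 focus genes was always included: Cyp1a1, Cyp1b1, Ahrr, Tiparp, Nqo1, Hmox1, Ptgs2, Il6, Cxcl1, Cxcl2, Ccl2, Tnf, Gja1, Mapk14, Mapkapk2, Dusp1, Zfp36, Fos, Egr1 and Cdkn1a. From the genes so taken, those whose call held in every setting run for named genes were preferred for the text.

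Counts of changed genes were run again with alternatives. Some changed the fit: only the compared groups, the replicate number as a block, array weights, and an intensity trend with robust estimation. Others changed the values or probes: quantile normalization, median centring, dim probes left out, the mean of the probes of a gene, and every probe tested. A 1.5-fold minimum, a gene-wise test without moderation, and each array left out in turn were also run. Named genes were not run again with every probe tested, the 1.5-fold minimum or the gene-wise test without moderation. Overlaps between comparisons were run again with the block, the 1.5-fold minimum, dim probes left out and each array left out in turn. List tests were run again with an estimated correlation, the block, fry and dim probes left out. Comparisons, lists, focus genes, the naming rule and these alternatives were chosen before the data were examined. Leaving out the 2 arrays of lowest weight was added after the data were seen. Overlaps between comparisons that share arrays were set against 50 simulations that kept the sharing. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

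The code was tested on simulated data made by adding known changes. For fluoranthene against DMSO at 4 h, with 22180 genes and 200 changed, 58.2% of genes changed 1.5-fold, 97% changed 2-fold and 100% changed 4-fold were recovered, and 0% of calls were unchanged genes. For the mixture at 8 h against DMSO at 4 h, a shift of 0.4 log2 in 1 list gave a camera adjusted p of 2.75e-86 for that list, and 1 other list passed.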

Results

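The series asked how a binary mixture of polycyclic aromatic hydrocarbons changed gene expression in mouse lung C10 cells, with inflammation, cell communication and the kinase p38 as its subjects. The labels describe C10 as a non-tumorigenic alveolar type II line. There were 18 arrays in 6 groups of 3: DMSO, 45 µM fluoranthene, the mixture (20 µM 1-methylanthracene with 20 µM fluoranthene) and the p38 inhibitor SB203580 (5 µM) with the mixture, all at 4 h, and the mixture with and without the inhibitor at 8 h. The series held no DMSO group at 8 h, no group with the inhibitor alone and no group with 1-methylanthracene alone. Changes at 8 h against DMSO at 4 h therefore carried time as well as exposure. Array medians lay between 3.35 and 3.43 log2, and arrays of the same group correlated at 0.9916 to 0.9964. The first 3 principal components held 29.7%, 13.9% and 8.14% of the variance. The labels call the arrays of a group biological replicates and do not say how the cultures were kept apart, so the p-values measure the spread between these samples. Precision is limited by 3 arrays per group. With 3 arrays against 3, chance alone keeps the groups of a gene from overlapping in 10% of genes. Changes are log2 differences with their standard error (SE), 3 arrays in each group, with limma p-values adjusted over 22180 genes.

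Marker lists were read as levels over all 18 arrays, exposed ones included, and levels of different probes do not rank genes by amount. The type II list had a median level of 3.24 log2 over all arrays, below the median of all probes (3.38), with 8 of 19 genes above that median and Abca3, a lamellar body transporter, at 7.17. The type I list had a median of 4.21 (13 of 15 genes above) and the mesenchymal list 6.57 (17 of 22 above), where the matrix gene Fn1 stood at 12.19. The keratin list had a median of 3.43, and Krt7 stood at 5.07. Club and ciliated, macrophage and endothelial lists had medians of 3.09, 3.18 and 3.21. In the gap junction list 6 of 19 genes lay above the median of all probes, with Gja1, which encodes connexin 43, at 9.45.

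**Figure D1:**
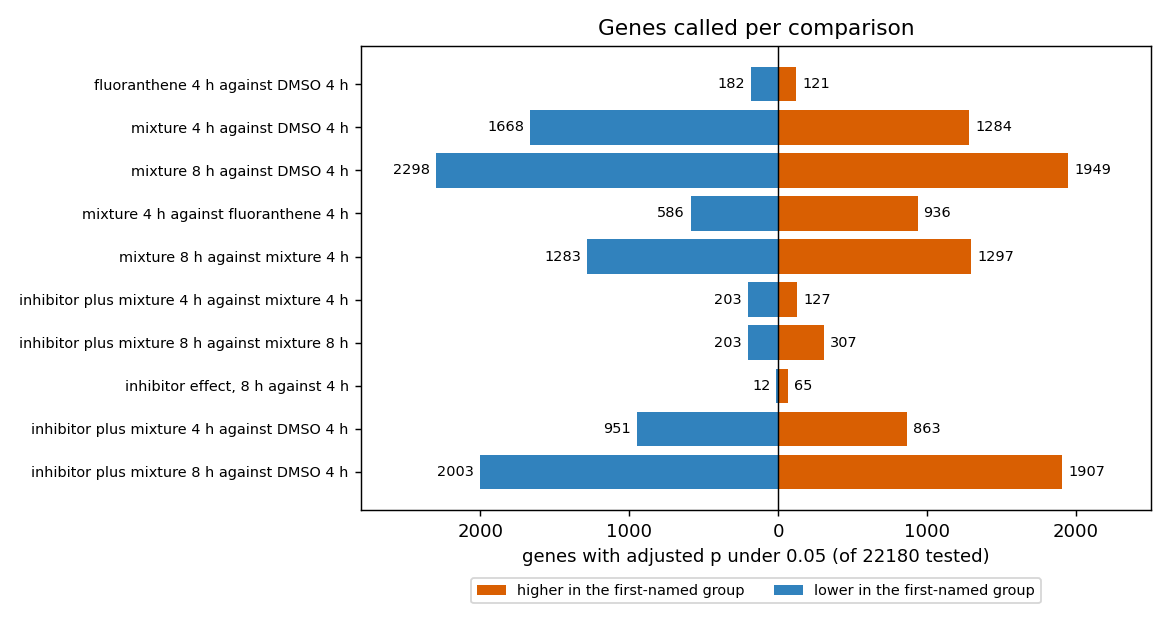
Number of genes changed in each comparison (limma adjusted p < 0.05, 3 arrays per group), with genes higher (right) and lower (left) in the first-named group on the x axis. The mixture changed 2952 genes at 4 h, fluoranthene 303, and the inhibitor 330 at 4 h and 510 at 8 h.

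Fluoranthene alone was compared with DMSO at 4 h to ask what this hydrocarbon did without its partner. Genes of cholesterol synthesis fell and genes of the aryl hydrocarbon receptor (AhR), the sensor of planar hydrocarbons, rose. The largest rise was in Ptx3, a secreted pattern recognition protein, at 8.57 ± 0.05 against 6.47 ± 0.12 (SD, n = 3), a change of 2.11 ± 0.10. The AhR target Tiparp rose by 1.52 ± 0.08 (adjusted p = 1.59e-08), the hydrocarbon-metabolizing Cyp1b1 by 1.20 ± 0.07 (adjusted p = 4.84e-08) and the quinone reductase Nqo1 by 1.23 ± 0.13 (adjusted p = 2e-05). Cyp1a1, the standard AhR reporter, was at 0.19 ± 0.20 (adjusted p = 0.735), but its level (2.95 with DMSO) lay below the median of all probes (3.38), where background limits the difference that can be seen. Ptgs2, which encodes cyclooxygenase 2, rose by 1.17 ± 0.13 (adjusted p = 7.69e-05), whereas Il6 (0.27 ± 0.13, adjusted p = 0.413), Cxcl1 (0.37 ± 0.11, adjusted p = 0.129) and Ccl2 (−0.24 ± 0.12, adjusted p = 0.433) were not called. Hmgcs1, an enzyme early in the sterol pathway, fell from 10.30 ± 0.10 to 8.48 ± 0.04 (SD, n = 3), a change of −1.82 ± 0.10. Sqle (−1.31 ± 0.09, adjusted p = 1.55e-07), Insig1 (−1.33 ± 0.08, adjusted p = 2.46e-08) and Lss (−1.15 ± 0.11, adjusted p = 1.53e-05) fell as well. The replication licensing gene Cdc6 fell by 1.12 ± 0.13 (adjusted p = 0.000135) and Id1, a target of bone morphogenetic protein signalling, by 0.81 ± 0.10 (adjusted p = 0.000135). Gja1 was at −0.01 ± 0.08 (adjusted p = 0.98).

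In this comparison 303 of 22180 genes changed, 121 higher and 182 lower, and 97 changed by at least 1.5-fold. The 3 arrays of the groups did not overlap in any of the 303. These genes were called on the same arrays, so this adds no support. Of the 38 gene lists 8 passed camera and 5 also passed with an estimated correlation. In the cholesterol list 15 of 19 measured genes fell (18 adjusted over the list alone), with a median of −1.11 and a camera adjusted p of 6.43e-51. The AhR list had 6 of 16 genes higher (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.11e-09). Hypoxia and glycolysis genes had 4 of 24 lower (15 adjusted over the list alone, camera adjusted p = 2.74e-11), and genes of fatty acid synthesis 3 of 18 (5 adjusted over the list alone, camera adjusted p = 0.000378). The TGF-beta list had 4 of 23 lower (7 adjusted over the list alone, camera adjusted p = 3.17e-05). The cell cycle list had 4 of 38 lower (1 higher and 10 lower adjusted over the list alone, camera adjusted p = 5.96e-05), but adjusted p = 0.235 with an estimated correlation. Immediate early (camera adjusted p = 0.388), cytokine (0.378) and gap junction lists (0.458) did not pass. Among early genes 1 of 29 was lower and 1 higher (5 and 4 adjusted over the list alone), the higher being Egr1 (0.75 ± 0.14, adjusted p = 0.0126). The count was 47 when only the compared groups were fitted, 12 with a gene-wise test without moderation, 665 with an intensity trend and 591 without dim probes. It was 167 without DMSO replicate 2, 170 without fluoranthene replicate 1 and 137 without the 2 arrays of low weight, and the share of higher genes was 39.9% as deposited, 51.5% after quantile normalization and 31.6% with median centring.

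The mixture was compared with DMSO at 4 h to ask what the binary exposure did, with inflammation named in the series title. Immediate early genes, feedback genes of the MAP kinases, cytokines and genes of the ATF4 and unfolded protein response rose. Ptgs2 rose to 10.52 ± 0.09 against 5.66 ± 0.31 (SD, n = 3), a change of 4.86 ± 0.13. The nuclear receptor gene Nr4a1 rose by 4.58 ± 0.11 (adjusted p = 4.53e-14) and the growth-response factor Egr1 by 4.56 ± 0.14 (adjusted p = 1.92e-12). Zfp36, whose protein destabilizes AU-rich messages, rose by 3.77 ± 0.18 (adjusted p = 2.57e-10), and Dusp6, a phosphatase of ERK, by 3.45 ± 0.15 (adjusted p = 1.06e-10). The chemokine genes Cxcl1 (2.63 ± 0.11, adjusted p = 6.64e-11), Ccl2 (2.13 ± 0.12, adjusted p = 3.05e-09) and Ccl7 (1.62 ± 0.14, adjusted p = 5.63e-07) and the cytokine Il6 (1.29 ± 0.13, adjusted p = 3.85e-06) rose, whereas Cxcl2 (−0.24 ± 0.16, adjusted p = 0.395) and Tnf (0.06 ± 0.11, adjusted p = 0.828) were not called. With DMSO Il6 (2.30), Cxcl2 (2.71) and Tnf (3.10) lay below the median of all probes (3.38) as well. Ddit3, the factor CHOP of the unfolded protein response, rose by 1.64 ± 0.08 (adjusted p = 1.84e-10), and the heme oxygenase Hmox1 by 0.76 ± 0.10 (adjusted p = 3.64e-05). The largest fall was in Txnip, a thioredoxin-binding protein that responds to glucose (−2.38 ± 0.14, adjusted p = 4.27e-09). The Wnt receptor Fzd2 (−1.44 ± 0.14, adjusted p = 1.6e-06) and the growth factor Fgf18 (−1.31 ± 0.11, adjusted p = 1.91e-07) fell. Among AhR genes Tiparp rose by 2.20 ± 0.08 (adjusted p = 2.49e-11) and Cyp1b1 by 1.21 ± 0.07 (adjusted p = 5.98e-09), and Cyp1a1 was at −0.17 ± 0.20 (adjusted p = 0.678). Among genes of cell communication the tight junction gene F11r fell by 0.37 ± 0.06 (adjusted p = 0.000589), and the cell cycle brake Cdkn1a rose by 0.95 ± 0.09 (adjusted p = 1.07e-06).

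With the mixture 2952 genes changed at 4 h, 1284 higher and 1668 lower, and 730 changed by at least 1.5-fold. Camera passed 15 lists, and 10 also passed with an estimated correlation. The immediate early list had 23 of 29 genes higher (24 adjusted over the list alone), a median of 1.32 and a camera adjusted p of 4.59e-40, with Fos at 2.49 ± 0.15 and Atf3 at 2.79 ± 0.08. MAP kinase feedback genes had 19 of 25 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 7.46e-22), with Dusp5 at 2.00 ± 0.12 and Dusp4 at 1.82 ± 0.17. The AU-rich message list had 15 of 23 higher and 2 lower (the same adjusted over the list alone, camera adjusted p = 1.89e-18). The ATF4 and unfolded protein list had 19 of 30 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 2.89e-24), with Cebpb at 1.62 ± 0.14 and Ppp1r15a at 1.57 ± 0.09. NF-kB feedback genes had 14 of 22 higher (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.12e-13), with the adhesion molecule Vcam1 at 1.69 ± 0.08, Nfkbiz at 1.45 ± 0.16 and Bcl3 at 1.36 ± 0.12.

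Cytokines and chemokines had 7 of 29 higher and 2 lower (the same adjusted over the list alone), with a camera adjusted p of 0.0035. AhR genes, with Serpinb2 (2.87 ± 0.13) counted among them, had 8 of 16 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 2.79e-09). The p53 targets had 10 of 24 higher and 4 lower (11 and 5 adjusted over the list alone, camera adjusted p = 0.00204). With an estimated correlation the camera adjusted p of that list was 0.0455. Plk3 was at 2.25 ± 0.13 and Plk2 at 1.76 ± 0.07. Clock genes had 8 of 17 higher and 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 9.92e-08), with Nr1d1 at 1.67 ± 0.08 and Per1 at 0.94 ± 0.08. Cholesterol genes had 16 of 19 lower (18 adjusted over the list alone), a median of −0.68 and a camera adjusted p of 4.56e-19. Hypoxia genes had 15 of 24 lower and 5 higher (16 and 5 adjusted over the list alone, camera adjusted p = 4.24e-05), but adjusted p = 0.0644 with an estimated correlation. Ribosome biogenesis genes had 9 of 34 higher (13 adjusted over the list alone, camera adjusted p = 4.62e-08), but adjusted p = 0.0776 with an estimated correlation. The NRF2 list had 7 of 24 higher and 6 lower (7 and 8 adjusted over the list alone) and did not pass (camera adjusted p = 0.833), though the cystine transporter Slc7a11 rose by 1.49 ± 0.15 and Txnrd1 by 0.78 ± 0.08. Gap junction genes (camera adjusted p = 0.385) and junction genes (0.523) did not pass, and no marker list did. Gja1 rose by 0.29 ± 0.08 (adjusted p = 0.0243), but its adjusted p was 0.101 with only the compared groups fitted, 0.0556 with median centring, 0.0997 without the 2 arrays of low weight, 0.0978 without DMSO replicate 1, and 0.0796 and 0.0744 without mixture replicates 2 and 3. The count of changed genes was 1634 with only the compared groups fitted and 1199 with a gene-wise test without moderation.

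**Figure D2:**
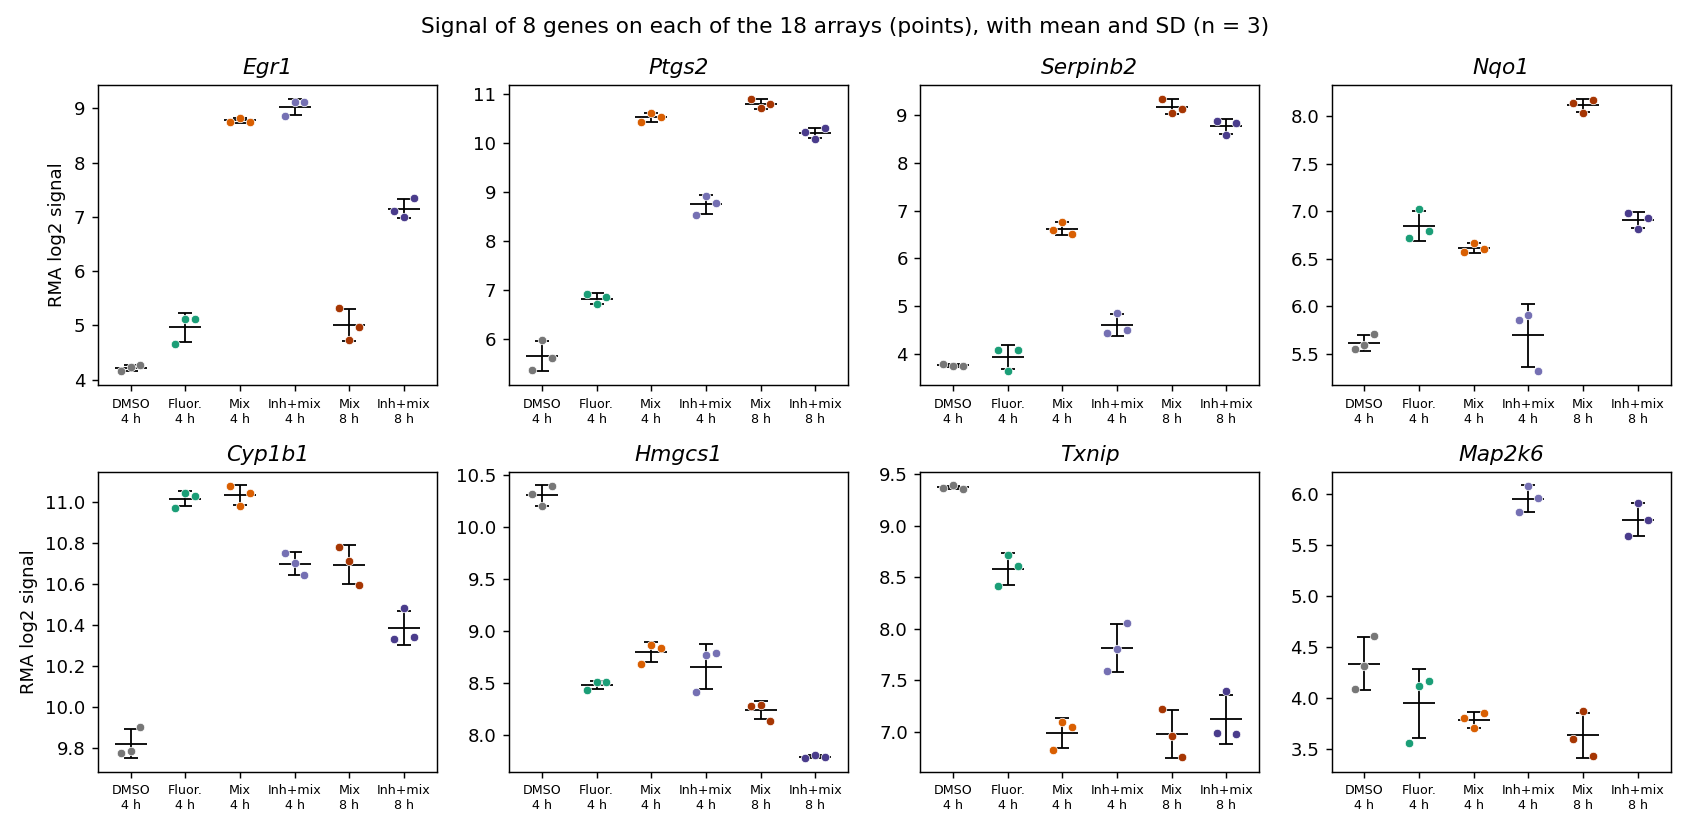
RMA log2 signal (y axis) of 8 genes on each of the 18 arrays by group (x axis), with group means and SD as error bars (n = 3). Ptgs2 stood at 5.66 with DMSO, 6.83 with fluoranthene and 10.52 with the mixture at 4 h.

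The mixture was compared with fluoranthene at 4 h to ask what the partner hydrocarbon, a methylated linear molecule, added. The groups differed in dose, with 45 µM fluoranthene alone against 20 µM of each compound. The mixture was higher in immediate early, NF-kB feedback and cytokine genes, and the differences in Cyp1b1 and Nqo1 were not called. Nr4a1 was higher with the mixture by 4.41 ± 0.11 (adjusted p = 8.2e-14), Egr1 by 3.81 ± 0.14 (adjusted p = 3.5e-11) and Ptgs2 by 3.69 ± 0.13 (adjusted p = 1.86e-11). Serpinb2, an inhibitor of plasminogen activators, was higher by 2.70 ± 0.13 (adjusted p = 8.07e-10), Ccl2 by 2.37 ± 0.12 (adjusted p = 1.2e-09) and Cxcl1 by 2.26 ± 0.11 (adjusted p = 7.03e-10). Txnip was lower by 1.59 ± 0.14 (adjusted p = 1.06e-06). Cyp1b1 rose by 1.20 with fluoranthene and 1.21 with the mixture, a difference of 0.02 (95% interval −0.14 to 0.17, adjusted p = 0.945). Nqo1 rose by 1.23 and 1.00, a difference of −0.24 (95% interval −0.50 to 0.03, adjusted p = 0.334). Tiparp rose by 1.52 and 2.20, a difference of 0.68 (95% interval 0.50 to 0.86, adjusted p = 5.75e-05), and Ptgs2 by 1.17 and 4.86, a difference of 3.69 (95% interval 3.41 to 3.97). Hmox1 was at 0.13 and 0.76, a difference of 0.63 (95% interval 0.43 to 0.83). Insig1, which holds back sterol synthesis, was higher with the mixture than with fluoranthene by 1.05 ± 0.08 (adjusted p = 9.95e-08).

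Between these groups 1522 genes differed, 936 higher and 586 lower with the mixture, 391 of them by at least 1.5-fold. Camera passed 14 lists, all higher with the mixture, and 7 also passed with an estimated correlation. Immediate early genes had 23 of 29 higher (26 adjusted over the list alone, median 1.35, camera adjusted p = 2.42e-53), with Btg2 at 2.97 ± 0.15 and Junb at 2.42 ± 0.18. MAP kinase feedback genes had 16 of 25 higher (20 adjusted over the list alone, camera adjusted p = 2.52e-26), with Dusp5 at 2.32 ± 0.12 and Errfi1 at 1.85 ± 0.09. ATF4 genes had 19 of 30 higher (20 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.25e-30), and NF-kB feedback genes 13 of 22 (16 adjusted over the list alone, camera adjusted p = 2.73e-16). Cytokines had 6 of 29 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.00717). Cholesterol genes had 7 of 19 higher than with fluoranthene (8 adjusted over the list alone, camera adjusted p = 1.65e-06), but adjusted p = 0.1 with an estimated correlation. The AhR list had 4 of 16 higher (the same adjusted over the list alone, camera adjusted p = 0.022), but adjusted p = 0.177 with an estimated correlation. Its largest difference was in Serpinb2 (2.70), which fluoranthene had not raised (0.17 ± 0.13, adjusted p = 0.642). The mean of the list was 0.25 and its median 0.04. Of the 303 genes changed with fluoranthene, 230 (75.9%) changed in the same direction with the mixture, 97 higher and 133 lower, against 20.7 for independent lists, and 7 changed in the opposite direction, against 19.6. The DMSO arrays are shared by both comparisons: over all genes r was 0.53, against 0.55 in simulations without any effect, and the covariance was 0.0263 against 0.00885. In 50 such simulations at most 2 genes were called in the same direction, but they held no effect to call in either comparison, so this count decides nothing. The overlap was not tested without shared DMSO arrays, so part of the excess may come from the shared controls. The count of differing genes was 574 with only the compared groups fitted, 434 with a gene-wise test without moderation and 961 without mixture 4 h replicate 1, and the share of higher genes was 61.5% as deposited, 53.3% after quantile normalization and 71.1% with median centring. The overlap was 463 without dim probes, 113 without the 2 arrays of low weight, 142 without DMSO replicate 2, 142 without fluoranthene replicate 1 and 71 at 1.5-fold.

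The mixture at 8 h was compared with DMSO at 4 h, since the series has no vehicle at 8 h. Ribosome biogenesis genes stood high, and cholesterol and cell cycle genes low. Serpinb2 rose from 3.76 ± 0.03 to 9.17 ± 0.16 (SD, n = 3), a change of 5.42 ± 0.13. The collagenase gene Mmp13 rose by 4.41 ± 0.10 (adjusted p = 2.18e-14) and Ptgs2 by 5.14 ± 0.13 (adjusted p = 6.34e-14). The antioxidant genes Hmox1 (1.71 ± 0.10, adjusted p = 1.31e-09) and Slc7a11 (3.75 ± 0.15, adjusted p = 2.81e-11) rose. Rrp12, which acts in ribosome export, rose by 1.38 ± 0.09 (adjusted p = 8.57e-09). Hmgcs1 fell by 2.06 ± 0.10 (adjusted p = 1.85e-10), the replication helicase gene Mcm6 by 1.29 ± 0.08 (adjusted p = 6.96e-09) and the tight junction scaffold Tjp1 by 0.82 ± 0.07 (adjusted p = 2.02e-07). Egr1 remained higher by 0.79 ± 0.14 (adjusted p = 0.000608), Cxcl1 by 0.54 ± 0.11 (adjusted p = 0.00161) and Ccl2 by 0.65 ± 0.12 (adjusted p = 0.000854), and Fos was at −0.00 ± 0.15 (adjusted p = 0.991). Gja1 was at 0.01 ± 0.08 (adjusted p = 0.967).

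Here 4247 genes changed, 1949 higher and 2298 lower, 1453 of them by at least 1.5-fold. Camera passed 17 lists, and 7 also passed with an estimated correlation. Ribosome biogenesis had 32 of 34 genes higher (the same adjusted over the list alone, median 0.65, camera adjusted p = 3.87e-31), with Ddx21 at 1.30 ± 0.08 and Polr1b at 1.22 ± 0.11. Cholesterol genes had 18 of 19 lower (the same adjusted over the list alone, median −1.25, camera adjusted p = 7.92e-26), and cell cycle genes 24 of 38 lower (31 lower and 1 higher adjusted over the list alone, median −0.40, camera adjusted p = 3.64e-15), with Uhrf1 at −1.21 ± 0.09 and Rrm2 at −1.07 ± 0.12. ATF4 genes had 22 of 30 higher and 1 lower (22 and 2 adjusted over the list alone, camera adjusted p = 1.27e-18), with Trib3 at 1.62 ± 0.09 and Mthfd2 at 1.48 ± 0.08. The AhR list, Serpinb2 included, had 8 of 16 higher and 1 lower (9 and 2 adjusted over the list alone, camera adjusted p = 5.59e-06). NRF2 genes had 13 of 24 higher and 6 lower (14 and 7 adjusted over the list alone, camera adjusted p = 8.73e-05), but adjusted p = 0.149 with an estimated correlation. Immediate early genes had 15 of 29 higher and 5 lower (18 and 5 adjusted over the list alone, camera adjusted p = 2.38e-07), but adjusted p = 0.0991 with an estimated correlation. Junction genes had 6 of 28 lower and 2 higher (8 and 2 adjusted over the list alone, camera adjusted p = 0.0225), but adjusted p = 0.142 with an estimated correlation. The count was 2479 with a gene-wise test without moderation.

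The mixture at 8 h was compared with the mixture at 4 h to ask how the response moved with time, without a vehicle at 8 h to remove time itself. Immediate early genes and cytokines were lower at 8 h, and NRF2 and ribosome biogenesis genes higher. Egr1 fell by 3.77 ± 0.14 (adjusted p = 8.54e-11), Nr4a1 by 3.74 ± 0.11 (adjusted p = 1.24e-12), Zfp36 by 3.17 ± 0.18 (adjusted p = 5.01e-09) and Fos by 2.49 ± 0.15 (adjusted p = 1.07e-08). The chemokines Cxcl1 (−2.09 ± 0.11, adjusted p = 3.14e-09) and Ccl2 (−1.48 ± 0.12, adjusted p = 4.23e-07) fell, while Ptgs2 was at 0.28 ± 0.13 (adjusted p = 0.229). Serpinb2 rose by 2.55 ± 0.13 (adjusted p = 3.08e-09), Slc7a11 by 2.26 ± 0.15 (adjusted p = 3.11e-08), Mmp13 by 2.07 ± 0.10 (adjusted p = 9.76e-10) and the stromelysin gene Mmp10 by 1.66 ± 0.14 (adjusted p = 3.99e-07). The glutathione synthesis gene Gclm (1.20 ± 0.07, adjusted p = 8.77e-09) and Hmox1 (0.95 ± 0.10, adjusted p = 3.66e-06) rose, and Tiparp fell by 1.20 ± 0.08 (adjusted p = 6.31e-08).

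Between the times 2580 genes changed, 1297 higher and 1283 lower at 8 h, 654 of them by at least 1.5-fold. Of the lists, 15 passed camera and 8 also passed with an estimated correlation. Immediate early genes had 20 of 29 lower (23 lower and 1 higher adjusted over the list alone, median −0.95, camera adjusted p = 6.85e-27). Ribosome biogenesis genes had 28 of 34 higher (31 adjusted over the list alone, median 0.46, camera adjusted p = 8.96e-28). Cell cycle genes had 21 of 38 lower (26 adjusted over the list alone, camera adjusted p = 2.26e-15), and cholesterol genes 14 of 19 (16 adjusted over the list alone, camera adjusted p = 2.92e-15). NRF2 genes had 9 of 24 higher and 2 lower (15 and 4 adjusted over the list alone, camera adjusted p = 3.27e-08). Cytokines had 8 of 29 lower (the same adjusted over the list alone, camera adjusted p = 0.00573). With an estimated correlation the camera adjusted p was 0.0445 for NRF2 genes and 0.0247 for cytokines. Clock genes had 7 of 17 lower (9 adjusted over the list alone, camera adjusted p = 1.02e-05), with Per1 at −1.25 ± 0.08. Wnt targets had 10 of 26 lower (12 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000415), but adjusted p = 0.0883 with an estimated correlation. The count was 1204 with a gene-wise test without moderation, and the share of higher genes was 50.3% as deposited and 43.2% after quantile normalization.

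**Figure D3:**
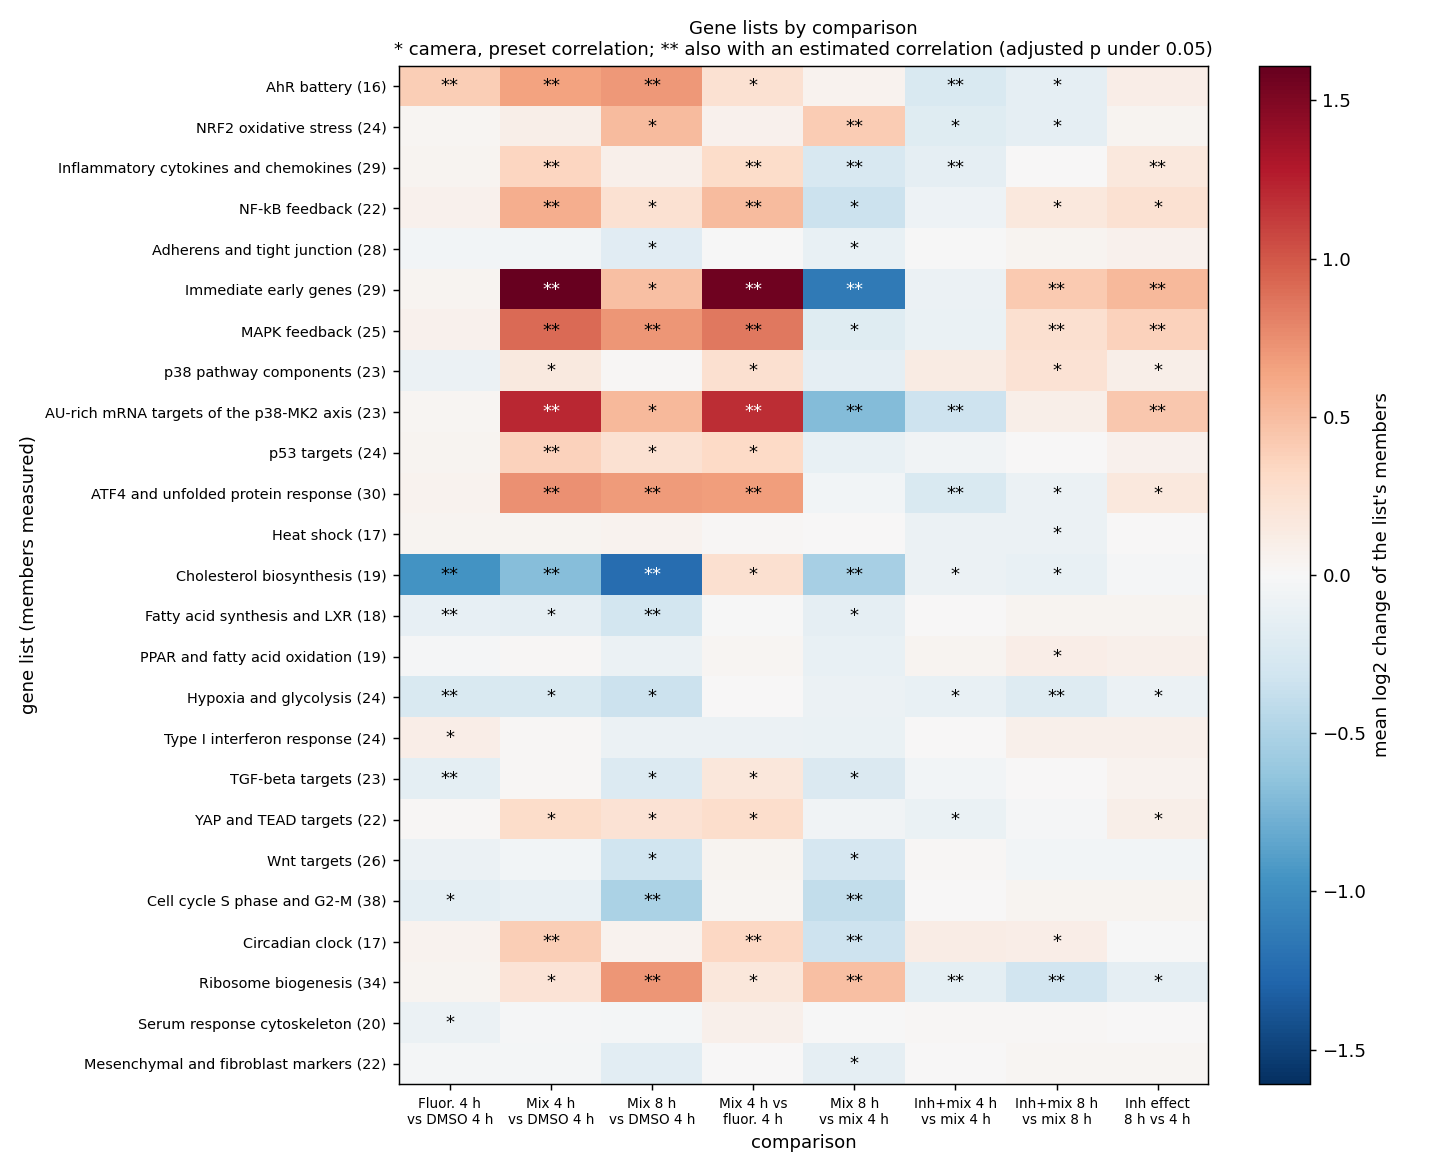
Mean log2 change of the members (colour) of the 25 gene lists that passed in any comparison (y axis, members measured in brackets) by comparison (x axis); asterisks mark camera adjusted p < 0.05. The immediate early list had a mean of 1.61 with the mixture at 4 h and 0.42 with the inhibitor at 8 h.

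The inhibitor with the mixture was compared with the mixture at 4 h to ask which changes p38 inhibition altered. Map2k6, whose product activates p38, rose from 3.78 ± 0.08 to 5.95 ± 0.13 (SD, n = 3), a change of 2.17 ± 0.16, and the factor Creb5 rose by 1.10 ± 0.15 (adjusted p = 0.000791). Serpinb2 fell by 2.03 ± 0.13 (adjusted p = 3.79e-07), Ptgs2 by 1.77 ± 0.13 (adjusted p = 1.19e-06), the hyaluronan synthase Has2 by 1.57 ± 0.12 (adjusted p = 1.39e-06) and Mmp13 by 1.54 ± 0.10 (adjusted p = 3.79e-07). Ptx3 (−1.13 ± 0.10, adjusted p = 4.55e-06), the heme oxygenase Hmox1 (−0.77 ± 0.10, adjusted p = 0.000396) and Nr4a1 (−0.91 ± 0.11, adjusted p = 0.000241) fell. Egr1 was at 0.25 ± 0.14 (adjusted p = 0.537), Fos at −0.38 ± 0.15 (adjusted p = 0.297), Zfp36 at −0.13 ± 0.18 (adjusted p = 0.855) and Cxcl1 at −0.38 ± 0.11 (adjusted p = 0.12). Ccl2 fell by 0.94 ± 0.12 (adjusted p = 0.000688) and Ccl7 by 0.83 ± 0.14 (adjusted p = 0.00569), but their adjusted p was 0.0577 and 0.11 with only the compared groups fitted. Il6 fell by 0.67 ± 0.13 (adjusted p = 0.0166), but its adjusted p was 0.113 with only the compared groups fitted and 0.0859, 0.0857, 0.0624 and 0.0696 without mixture replicate 1, mixture replicate 2, inhibitor replicate 1 and inhibitor replicate 3. Gja1 was at −0.30 ± 0.08 (adjusted p = 0.0855), Mapk14, which encodes p38 alpha, at 0.30 ± 0.08 (adjusted p = 0.0734), and Tiparp at 0.22 ± 0.08 (adjusted p = 0.272).

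With the inhibitor 330 genes changed at 4 h, 127 higher and 203 lower, 92 of them by at least 1.5-fold. Of the lists, 9 passed camera and 5 also passed with an estimated correlation. ATF4 genes had 6 of 30 lower (17 adjusted over the list alone, median −0.21, camera adjusted p = 4.19e-17), with Ddit4 at −0.88 ± 0.09. AU-rich messages had 8 of 23 lower and 1 higher (12 and 2 adjusted over the list alone, camera adjusted p = 1.11e-09), with Plaur at −0.79 ± 0.12, and cytokines 5 of 29 lower (6 adjusted over the list alone, camera adjusted p = 0.00107). AhR genes had 4 of 16 lower (7 lower and 2 higher adjusted over the list alone, camera adjusted p = 3.14e-05). Ribosome genes had 4 of 34 lower (13 adjusted over the list alone, camera adjusted p = 5.17e-10). With an estimated correlation the camera adjusted p was 0.0225 for AhR genes and 0.0463 for ribosome genes. The 4 AhR-list genes were Serpinb2 (−2.03), which is counted in that list, Nqo1 (−0.92), Ahr (−0.41) and Cyp1b1 (−0.33). The AhR list had a mean of −0.25 and a median of −0.11. NRF2 genes had 7 of 24 lower and 1 higher (7 and 2 adjusted over the list alone, camera adjusted p = 4.33e-05), but adjusted p = 0.129 with an estimated correlation. Hypoxia genes passed downward (5 of 24 lower, the same adjusted over the list alone, camera adjusted p = 0.0369) with a mean of −0.12 and a median of 0.02, and adjusted p = 0.326 with an estimated correlation. The immediate early (camera adjusted p = 0.0663), MAP kinase feedback (0.0537) and gap junction lists (0.387) did not pass. Members of the first pair changed in both directions. Early genes had 2 of 29 higher and 4 lower (3 and 6 adjusted over the list alone), with Jun at 0.73 ± 0.10 and Klf4 at −1.07 ± 0.12. Feedback genes had 5 of 25 higher and 7 lower (5 and 9 adjusted over the list alone), with Dusp8 at 0.74 ± 0.12 and Phlda1 at −0.81 ± 0.14. The count was 29 with only the compared groups fitted, 7 with a gene-wise test without moderation, 775 with an intensity trend, 656 without dim probes and 196 with median centring, and the share of higher genes was 38.5% as deposited, 47.9% after quantile normalization and 44.9% with median centring. Leaving out any of the 6 arrays lowered it: 148, 153 and 203 without mixture replicates 1, 2 and 3, and 152, 215 and 159 without inhibitor replicates 1, 2 and 3.

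Of the 330 genes, 234 (70.9%) moved opposite to their change with the mixture against DMSO, 162 raised by the mixture and lower with the inhibitor and 72 the reverse, and 17 moved in the same direction. These 234 were 7.93% of the 2952 genes changed by the mixture, and independent lists would share 21.3 in opposite directions and 22.6 in the same direction. The mixture arrays are in both comparisons, which alone gives a negative relation: r over all genes was −0.50, against −0.26 in simulations with no inhibitor effect, and the covariance was −0.0235 against −0.0103. In 50 such simulations at most 46 genes moved back. They held no inhibitor effect to call, so this count does not tell whether genes changed by the inhibitor tend to move back. Against DMSO at 4 h the inhibitor with the mixture changed 1814 genes, 863 higher and 951 lower, 653 with only the compared groups fitted and 316 with a gene-wise test without moderation, and the share of higher genes was 47.6% as deposited and 51.9% after quantile normalization. The number moved back was 478 without dim probes and 63 at 1.5-fold, 105, 109 and 153 without mixture replicates 1, 2 and 3, and 107, 148 and 115 without inhibitor replicates 1, 2 and 3.

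The same comparison at 8 h asked what the inhibitor altered later. Immediate early and MAP kinase feedback genes were higher with the inhibitor, and ribosome biogenesis and hypoxia genes lower. Egr1 rose by 2.14 ± 0.14 (adjusted p = 4.61e-07), Jun by 1.31 ± 0.10 (adjusted p = 1.64e-06) and Map2k6 by 2.12 ± 0.16 (adjusted p = 1.64e-06). Dusp1, a phosphatase of p38 and JNK, rose by 0.94 ± 0.10 (adjusted p = 3.98e-05), and Nfkbia, the inhibitor of NF-kB, by 0.95 ± 0.13 (adjusted p = 0.000427). Has2 fell by 1.34 ± 0.12 (adjusted p = 1.1e-05), Mmp13 by 1.29 ± 0.10 (adjusted p = 1.64e-06), the tetraspanin gene Cd53 by 1.29 ± 0.12 (adjusted p = 1.77e-05) and Nqo1 by 1.21 ± 0.13 (adjusted p = 4.62e-05). Ptgs2 fell by 0.60 ± 0.13 (adjusted p = 0.0234), but leaving out any of the 6 arrays gave an adjusted p of 0.0508 to 0.113. Ccl2 rose by 0.49 ± 0.12 (adjusted p = 0.0483), but its adjusted p was 0.0765 with median centring and 0.0731 to 0.203 without any of the 6 arrays. Il6 was at −0.15 ± 0.13 (adjusted p = 0.773), Cxcl1 at 0.09 ± 0.11 (adjusted p = 0.86) and Gja1 at −0.02 ± 0.08 (adjusted p = 0.962). Mapk14 rose by 0.32 ± 0.08 (adjusted p = 0.043), a call close to the limit of 0.05. With the mixture against DMSO at 4 h it had been at −0.26 ± 0.08 (adjusted p = 0.0358).

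With the inhibitor 510 genes changed at 8 h, 307 higher and 203 lower, 136 of them by at least 1.5-fold. Of the lists, 13 passed camera and 4 also passed with an estimated correlation. Immediate early genes had 11 of 29 higher (16 adjusted over the list alone, median 0.35, camera adjusted p = 2.01e-16), and MAP kinase feedback genes 9 of 25 higher (10 adjusted over the list alone, camera adjusted p = 1.18e-08), with Dusp8 at 0.84 ± 0.12 and Dusp14 at 0.73 ± 0.10. Ribosome biogenesis genes had 14 of 34 lower (27 adjusted over the list alone, median −0.31, camera adjusted p = 2.28e-27), with Dkc1 at −0.68 ± 0.09 and Rrp12 at −0.57 ± 0.09. Hypoxia genes had 7 of 24 lower (15 adjusted over the list alone, camera adjusted p = 3.57e-10), with Hk2 at −0.63 ± 0.10 and Vegfa at −0.55 ± 0.07. NF-kB feedback genes had 4 of 22 higher (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000377), but adjusted p = 0.245 with an estimated correlation. The p38 component list had 5 of 23 higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.000337), but adjusted p = 0.151 with an estimated correlation. The AhR list had 4 of 16 lower and 1 higher (5 and 1 adjusted over the list alone, camera adjusted p = 0.0354), but adjusted p = 0.214 with an estimated correlation. Cytokines (camera adjusted p = 0.875) and AU-rich messages (0.331) did not pass. The count was 253 with only the compared groups fitted, 27 with a gene-wise test without moderation, 968 with an intensity trend, 880 without dim probes and 864 with array weights. It was 332, 254 and 279 without mixture replicates 1, 2 and 3, and 319, 297 and 249 without inhibitor replicates 1, 2 and 3.

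Of the 510 genes, 283 (55.5%) moved opposite to their change with the mixture at 8 h against DMSO at 4 h, 132 raised by the mixture and lower with the inhibitor and 151 the reverse, and 95 moved in the same direction. These were 6.66% of 4247 genes, and independent lists would share 49.6 in opposite directions and 48 in the same direction. The mixture arrays are shared here too: r was −0.32, against −0.18 in simulations with no inhibitor effect, and the covariance was −0.0177 against −0.00836. In 50 such simulations at most 25 genes moved back and at most 18 in the same direction. Here too they held no inhibitor effect to call, so these counts do not tell the direction of genes that the inhibitor changed. Against DMSO at 4 h the inhibitor with the mixture at 8 h changed 3910 genes, 1907 higher and 2003 lower, and 2269 with a gene-wise test without moderation. The number moved back was 491 without dim probes and 51 at 1.5-fold, 152 and 159 without mixture replicates 2 and 3, and 160 and 151 without inhibitor replicates 2 and 3.

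The change with the inhibitor at 8 h was compared with that at 4 h to ask whether the inhibitor acted differently with time. As lists, early genes and AU-rich messages had a more positive change with the inhibitor at 8 h than at 4 h. The levels themselves could be lower at 8 h, as for Egr1 with the inhibitor (7.15 against 9.03). The change of Egr1 went from 0.25 at 4 h to 2.14 at 8 h, while that of Ptgs2 went from −1.77 to −0.60, a smaller fall. Egr1 differed by 1.89 ± 0.20 (adjusted p = 0.000347), Serpinb2 by 1.62 ± 0.19 (adjusted p = 0.000758), Nr4a1 by 1.52 ± 0.15 (adjusted p = 0.000191) and Ptgs2 by 1.18 ± 0.19 (adjusted p = 0.00839). Ccl2 differed by 1.43 ± 0.18 (adjusted p = 0.00107) and Errfi1, a feedback inhibitor of the EGF receptor, by 1.19 ± 0.12 (adjusted p = 0.000248). Wnt9a, a Wnt ligand, differed in the other direction (−0.83 ± 0.12, adjusted p = 0.00589). In total 77 genes differed, 65 higher and 12 lower. Of the lists, 10 passed camera and 4 also passed with an estimated correlation. Immediate early genes had 5 of 29 higher (17 adjusted over the list alone, median 0.45, camera adjusted p = 1.49e-20) and AU-rich messages 5 of 23 (13 adjusted over the list alone, camera adjusted p = 1.54e-12). MAP kinase feedback genes had 3 of 25 higher (11 adjusted over the list alone, camera adjusted p = 4.21e-12). Cytokines had 2 of 29 higher (the same adjusted over the list alone, camera adjusted p = 0.00491). Both of these cytokine genes, Ccl2 and Lif, are also in the AU-rich list, and Lif is in the feedback list as well. Fos is in the early and AU-rich lists. NF-kB feedback genes had 1 of 22 higher (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.34e-07), but adjusted p = 0.0811 with an estimated correlation. The count was 49 with only the compared groups fitted, 306 with an intensity trend, 170 without dim probes, 134 with array weights and 41 with median centring. It was 46 and 39 without 4 h mixture replicates 1 and 2, 36 and 41 without 4 h inhibitor replicates 1 and 3, 37 and 43 without 8 h mixture replicates 2 and 3, and 40 and 35 without 8 h inhibitor replicates 1 and 3.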

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

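Chosen only after the result was seen were the tests of all 29 early genes (1 array left out, and random lists), the count at 2-fold without a p-value, and the tests on the amount of fluoranthene and on 1-methylanthracene by itself, and the tests without shared arrays were added after the count of moved-back genes had been compared with simulations. No array was tested against its own group of 3, and with the spread pooled over all arrays the lowest weights were 0.442 (DMSO replicate 1) and 0.463 (fluoranthene replicate 1).

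The change with the inhibitor differed between 8 h and 4 h in 77 genes. In 100 splits of the arrays within each time, 2 called as many genes, the real one (77) included. The exchanged arrays kept their real changes with the inhibitor, so the splits cannot tell whether chance made the difference between the times. The highest other split (79) exchanged the inhibitor labels of all 8 h arrays and of 1 array at 4 h. Such an exchange turns the difference of the changes into their sum. In every setting run for named genes, the call was kept for Egr1 (1.89), Serpinb2 (1.62), Nr4a1 (1.52), Ccl2 (1.43), Hivep2 (1.31) and Dusp5 (1.30). It was also kept for Errfi1 (1.19), Ptgs2 (1.18), Angptl4 (1.07), Wnt9a (−0.83) and Anxa8 (−0.59). The calls of Fam110c (1.12), Cdc6 (−1.0), Cd53 (−0.93), Edn1 (−0.82), Jrkl (−0.74), Znrf3 (−0.68), Rpusd1 (−0.63), Pik3ip1 (−0.59), Cmss1 (−0.57), Fos (1.05) and Cdkn1a (0.66) ended when any of 6 to 11 of the 12 arrays was left out in turn. The highest adjusted p was 0.0944 for Fam110c, 0.0845 for Cdc6, 0.0677 for Cd53, 0.0756 for Edn1, 0.0778 for Jrkl, 0.0561 for Znrf3, 0.0774 for Rpusd1, 0.0949 for Pik3ip1, 0.132 for Cmss1, 0.146 for Fos and 0.0972 for Cdkn1a. With the mean of its probes Rpusd1 had an adjusted p of 0.682.

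Of the 77, 5 were immediate early genes (Fos, Egr1, Atf3, Nr4a1 and Klf4), with a median difference of 1.05 log2. An array that carried the shift of the whole list would take the median of its 29 measured genes (0.45) down by more than 50% when left out, but the lowest such median was 0.39 (SD over the arrays 0.03). A scale difference between arrays would move genes of like level alike, but the highest median of 10000 random lists matched on level was 0.17. A signal ceiling at 4 h would hide a rise there, but these genes lay a median of 3.51 log2 under 12.12, a level near the brightest probes of the 4 h mixture arrays (SD between the genes 1.20), where 1 log2 had been set as the limit. For these 5 genes 1 array out of place stays open, since their medians with 1 array left out (lowest 0.93) and under other scalings (lower 1.04) were taken over genes chosen for the difference and decide nothing, and so does a change in the action of the inhibitor with time, without an inhibitor group free of the mixture.

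Of the genes changed by the mixture, 7.93% moved back with the inhibitor at 4 h and 6.66% at 8 h. The change at 8 h was taken against DMSO at 4 h and so carried time. In the same direction moved 17 genes at 4 h and 95 at 8 h, against at most 1 and 18 in simulations with no inhibitor effect. Those simulations had no inhibitor effect to call, so these counts do not tell whether genes changed by the inhibitor tend to move back. Chance in the shared mixture arrays would vanish when no array is shared, but the gap between mixture-lowered and mixture-raised genes in their change with the inhibitor was at least 0.26 log2 at 4 h and 0.11 log2 at 8 h (SD over the 3 arrays 0.01 at both times). With 1 mixture array in each comparison and none shared, the highest covariance over genes was −0.00974 at 4 h and −0.00745 at 8 h, so no single mixture array carried the relation. The 3 gaps of a time share the DMSO and inhibitor arrays, so their SD is not a spread of independent repeats. A shift common to all 3 mixture arrays of a time would pass both tests and stays open. The moved-back genes could reflect p38-dependent expression, an action of the inhibitor apart from the mixture, such a shift, or several of these. The series has neither a group with the inhibitor alone nor a p38 inhibitor of another structure, and cannot separate these.

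Fluoranthene changed fewer genes than the mixture at 4 h, a ratio of 9.74 in counts (7.59 to 18.1 with 1 array left out). Leaving out the 2 arrays of low weight gave 20, which decides nothing about noise, since it also took more arrays from the fluoranthene comparison. Noise hiding changes of equal size would leave as many genes at least 2-fold from DMSO when no p-value is asked, but there were 24 with fluoranthene and 168 with the mixture, and the ratio was at least 6.58 with 2 arrays of each (SD 0.292). The groups also differed in fluoranthene (45 µM alone, 20 µM in the mixture), and without a group of 20 µM alone the part of its amount was not tested. Whether 1-methylanthracene by itself or the combination raised the count could not be told, with 0 groups of 1-methylanthracene alone.

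For comparisons of 3 against 3, the 10 possible splits are too few for a share under 0.05. In each, 1 of the 10 splits, the real one, called as many genes as the real count, and the highest other split called 4 for fluoranthene (real 303), 1 for the mixture at 8 h against DMSO (real 4247) and 0 for the mixture at 4 h (real 2952), the mixture against fluoranthene (1522), 8 h against 4 h (2580), the inhibitor at 4 h (330) and 8 h (510) and the inhibitor groups against DMSO (1814 and 3910).

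The 17513 probes without a single gene symbol were tested apart. With the mixture 240 changed at 4 h (111 higher, 129 lower, largest 3.25 log2) and 458 at 8 h against DMSO at 4 h (282 higher, 176 lower, largest 3.30).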

How the results depend on the processing

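Counts of changed genes are given in the order fluoranthene, mixture 4 h, mixture 8 h against DMSO, mixture against fluoranthene, mixture 8 h against 4 h, inhibitor 4 h, inhibitor 8 h, difference of inhibitor changes, and inhibitor with mixture at 4 h and 8 h against DMSO (303, 2952, 4247, 1522, 2580, 330, 510, 77, 1814, 3910). Leaving out the 2 arrays of low weight (DMSO replicate 1, weight 0.442, and fluoranthene replicate 1, 0.463) was chosen after the data were seen. With only the compared groups fitted, fluoranthene gave 47, mixture 4 h 1634, mixture against fluoranthene 574, inhibitor 29 and 253, the difference 49 and inhibitor with mixture at 4 h against DMSO 653. A gene-wise test without moderation gave 12, 1199, 2479, 434, 1204, 7, 27, 316 and 2269, the difference not being run. An intensity trend gave fluoranthene 665, inhibitor 775 and 968 and the difference 306. Without dim probes fluoranthene gave 591, inhibitor 656 and 880, the difference 170, moved-back genes 478 and 491 and the overlap of fluoranthene and mixture 463. Array weights gave inhibitor 8 h 864 and the difference 134, and median centring inhibitor 4 h 196 and the difference 41. At 1.5-fold the counts were 97, 730, 1453, 391, 654, 92, 136, 64, 441 and 1265, moved-back genes 63 and 51 and the overlap 71. Without the 2 arrays of low weight fluoranthene gave 137 and the overlap 113. With an estimated correlation 50 of 101 list tests passed. The cause of these moves was not tested.

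With 1 array left out in turn the ranges were fluoranthene 167 to 254, mixture 4 h 2276 to 2573, mixture 8 h 3581 to 3932, mixture against fluoranthene 961 to 1161, mixture 8 h against 4 h 1928 to 2130, inhibitor 4 h 148 to 215, inhibitor 8 h 249 to 332, the difference 35 to 76, inhibitor with mixture against DMSO 1235 to 1461 at 4 h and 3146 to 3704 at 8 h, moved-back genes 105 to 229 at 4 h and 151 to 287 at 8 h, and the overlap 142 to 220. Of 757 named-gene results 679 were called, and 153 calls were lost with only the compared groups fitted, 50 with median centring, 36 without the 2 arrays of low weight, 30 with the replicate block, 14 with the mean of the probes, 8 with array weights, 8 with quantile normalization and 4 with an intensity trend. With single arrays left out in turn 139 of the 679 calls were lost at least 1 time, in 603 reruns of a gene without an array. No called named gene and no passing list test changed direction in the settings run for them. The share of higher genes did change sides in some comparisons, as given below.

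With the replicate number as a block the counts were 250, 2883, 4174, 1432, 2472, 245, 456, 59, 1747 and 3826. Pairing was checked on 45 pairs of arrays with the same number, whose correlation ran from −0.17 to 0.22 with a median of −0.0021, and 5 of 18 arrays correlated best with their own number, so the numbers do not pair the arrays. Quantile normalization moved the median change by at most 0.016 log2 and median centring by at most 0.029, and quantile normalization took the share of higher genes from 39.9% to 51.5% with fluoranthene (31.6% with median centring), from 61.5% to 53.3% for the mixture against fluoranthene (71.1% with median centring), from 38.5% to 47.9% with the inhibitor at 4 h, from 50.3% to 43.2% for the mixture at 8 h against 4 h and from 47.6% to 51.9% for the inhibitor with mixture at 4 h against DMSO. Signal over background limits the size of changes in dim genes, since RMA log2 differences shrink near background.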

Other observations

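The 7 gene families in this part were chosen after the data were seen, and so was the AhR hypothesis, whose criterion was changed after a first version had been run. Their p-values were adjusted over 56 family tests.

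Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were raised in 13 of 15 genes by the mixture at 8 h against DMSO at 4 h (median 0.69, camera adjusted p = 6.77e-14, and adjusted p = 0.0282 with an estimated correlation), with Cars at 1.07 ± 0.08 and Tars at 0.97 ± 0.06. At 4 h 11 of 15 were higher and 1 lower (median 0.32, camera adjusted p = 1.14e-07), but adjusted p = 0.0939 with an estimated correlation. Subunits of RNA polymerases I and III had 7 of 13 higher and 1 lower at 8 h (camera adjusted p = 2.02e-05), but adjusted p = 0.139 with an estimated correlation, and initiation factors 18 of 51 higher and 2 lower (camera adjusted p = 3.56e-05), but adjusted p = 0.22 with an estimated correlation. Matrix metalloproteinases did not pass in any comparison, with 3 of 22 higher and 6 lower for the mixture at 8 h against DMSO (median −0.07, camera adjusted p = 0.86), 3 higher and 1 lower at 8 h against 4 h (0.427) and 1 lower with the inhibitor at 4 h (0.322) and at 8 h (0.425). Tubulins had 3 of 13 higher with the inhibitor at 8 h (median 0.31, camera adjusted p = 3.9e-05, and adjusted p = 0.0282 with an estimated correlation), with Tubb2a at 0.85 ± 0.13, Tuba1a at 0.84 ± 0.13 and Tubb5 at 0.40 ± 0.07.

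A first hypothesis was that SB203580 acted on the AhR, so that the genes raised by both exposures would fall together with the inhibitor. At 4 h 4 of 6 such genes were lower at an unadjusted p below 0.05, Cyp1b1 (−0.33, limma adjusted p = 0.0328), Nqo1 (−0.92, 0.000937), Aldh3a1 (−0.39, 0.226) and Nfe2l2 (−0.19, 0.279), while Xdh was at −0.10 and Tiparp at 0.22 (95% interval 0.04 to 0.40). At 8 h Nqo1 (−1.21, limma adjusted p = 4.62e-05), Aldh3a1 (−0.66, 0.0176) and Cyp1b1 (−0.31, 0.0352) were lower, Nfe2l2 was higher (0.37, 0.0135), and Xdh (0.07) and Tiparp (−0.09) were not called. Of these 8 h calls only that of Nqo1 held in every setting run for named genes. With 1 array left out the adjusted p reached 0.0888 for Aldh3a1, 0.153 for Cyp1b1 and 0.0817 for Nfe2l2. The 6 genes were thus not all lower at 4 h, as a fall of all of them would ask. A shared fall of some of them could not be told from separate changes. The call of Cyp1b1 ended with only the compared groups fitted (adjusted p = 0.205), with the replicate block, with median centring and without any of the 6 arrays (up to 0.135), and that of Nqo1 with only the compared groups fitted (0.0752). An inhibitor group without the mixture, or a p38 inhibitor of another structure, would test this.

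A further hypothesis was that Zfp-named genes fell as a family with the mixture at 4 h. Their median over 366 genes was −0.04, the 11th percentile of 10000 matched random lists (95% of them between −0.052 and 0.001), and camera gave an adjusted p of 0.972 with an estimated correlation. Of the 366 genes 26 were higher and 28 lower, so a fall of the family was not shown, and drift of dim genes and replicate noise both remained possible.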
